A study of Mus musculus with 12 samples.

How the data were processed

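Total RNA was taken from 12 cultures of mouse embryonic fibroblasts, amplified, biotin-labelled and hybridised to 1 array each, per the labels' protocols. The groups were p53(-/-) primary, p53(-/-) transformed, p53(246/-) primary and p53(246/-) transformed, with 3 arrays each, taken from the genotype and state in the labels. All 12 columns of the deposited table matched a sample, and 0 columns were left without one. The labels tie the transformed clones to the primary clones they came from, so the primary and transformed culture with the same genotype and replicate number were treated as 1 clone, with 6 clones in all. Nothing used here says that each clone came from a different litter. The p-values of the linear model measure the spread between the arrays of these clones within a group. The 2 arrays of a clone counted there as nearly independent. The clone labels hold a number before a hyphen whose meaning they do not give: 1 number is shared by all 3 p53(-/-) clones, the p53(246/-) clones have 2, and 0 occur in both genotypes, so whatever it marks lies within a genotype.

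The deposited values were processed by the authors and read here as log2 signal, since they ran from 2.63 to 13.5. The log base, background correction, normalization and centring are not given in the sources used here. Partek 6.5 and the genome build mm8 are named in the submitters' processing notes, without their role, and the series text names a mixed model analysis. Signals are 1-colour, so a higher value was taken as more RNA. Column medians for replicates 1, 2 and 3 were 5.47, 5.44 and 5.52 in p53(-/-) primary, 5.59, 5.58 and 5.53 in p53(-/-) transformed, 5.47, 5.47 and 5.53 in p53(246/-) primary and 5.57, 5.49 and 5.54 in p53(246/-) transformed cultures. No pair of arrays held the same values: at most 0.441% of probes lay within 0.001 of each other. Detection calls were not used here, so signal over background is unknown.

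The table held 23332 probes. A platform annotation gave 1 gene symbol for 14996 probes, several for 1019 and none for 7317. Entrez numbers of 14941 probes matched a mouse gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other, and 0 symbols changed. Probes with 1 symbol were kept, and the probe with the highest mean over the arrays stood for the 135 genes with several, of which 1 had probes called in opposite directions by transformation. This left 14860 genes. Trp53 was not analysed here.

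A linear model with the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), with the clone as a random block through duplicateCorrelation. The consensus correlation was -0.0021, so the fit took the 2 arrays of a clone as nearly independent, the residual degrees of freedom 8 and the prior degrees of freedom 4.61. Limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison, gave calls at an adjusted p under 0.05. The SE beside a gene's change is the moderated SE of this fit, with the spread pooled over the 4 groups. It is therefore the same for transformation in both genotypes and is not the spread of the clones compared. The comparisons were transformed minus primary in each genotype and averaged over both, p53(246/-) minus p53(-/-) in each state and averaged over both, and the difference between the genotypes' responses. The pairing comes from the labels. Within p53(-/-), the deviations from the group means of primary and transformed cultures with the same number correlated at -0.136, 0.0928 and -0.177 across genes, and within p53(246/-) at 0.116, 0.202 and 0.210; a culture correlated best with its own number in 3 of 6 clones. A replicate number shared across genotypes pairs nothing.

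The samples' groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. The rule named, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those with 1 sign in all 3 clones (transformation) or with groups that do not overlap (genotype), or, where none passed, the 5 with the smallest p. It also named up to 2 rising and 2 falling members per list, or up to 2 members with the smallest p where none passed, and the sex-linked genes; gene models without a curated name were counted and not named. The text describes part of the genes so named.

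The lists were p53 target genes, the p53 family, DNA replication and E2F targets, mitosis, cyclin-dependent kinase inhibitors and pocket proteins, RAS and ERK output, fibroblast extracellular matrix, contractile and SRF or YAP target genes, mesenchymal identity, epithelial genes, interferon-stimulated genes, MHC class I antigen presentation, inflammatory cytokines and senescence secretome, imprinted growth genes, Hox genes, glycolysis and hypoxia, cholesterol synthesis, amino acid response, NRF2 target genes, ribosome biogenesis and MYC targets, genes reported to be raised by mutant p53, and markers of endothelium, macrophages and leukocytes, skeletal muscle, nerve and glia, cartilage and bone, adipocytes, erythroid cells and keratinocytes, with sex-linked genes as a check of the clones. They were written from general knowledge, and some genes are in 2 lists. The 28 lists with at least 5 measured genes were tested with limma's camera on the moderated statistics at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. They were tested again with a correlation estimated per list, and with fry. Camera compares a list with the other genes; fry's directional test asks whether the members move, on balance, one way, its mixed test whether they change in either direction, and neither compares them with other genes. List means per clone were compared by exact two-sided permutation over 20 arrangements, for which 3 against 3 allows no p under 0.1. These p were not adjusted over the 28 lists, so some lists can reach 0.1 by chance.

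The fit was tested on simulated data for 14860 genes, with 100 genes changed at each size, without and with a shared clone effect. For transformation in p53(-/-) cells it recovered 89% and 98% of 2-fold changes and 51% and 70% of 1.5-fold changes, with 7 and 8 false calls. In p53(246/-) cells it recovered 88% and 96%, and 60% and 69%, with 12 and 8 false calls. For genotype in primary cells the shares were 84% and 87%, and 52% and 57% (8 and 6 false calls), and in transformed cells 91% and 91%, and 48% and 58% (9 and 10 false calls). For the difference in response they were 55% and 81%, and 20% and 27% (4 and 2 false calls). The list test called 1 of 1 raised list and 0 of 27 unchanged lists. The simulated genes varied independently and the lists were drawn at random. This therefore does not test the preset correlation on lists whose genes vary together. Of the unchanged genes, 5.01% had an unadjusted p under 0.05 in the unmoderated model.

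The alternatives were no block, the clone or replicate number as a fixed block, quantile normalization, median centring, leaving out the lowest 33.3% of probes by mean signal, averaging a gene's probes, a trended and robust prior, an unmoderated mixed model with the clone as random term, a 2-fold minimum, only the 6 arrays compared, and each clone left out in turn. Leaving out the 3 arrays of narrowest spread, the lists after median centring, the number of the clone label as a random block (consensus correlation 0.0455) and, for genotype averaged over states, the mean of a clone's 2 arrays as 1 value were added after seeing the data.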

Results

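Gene expression was measured in 12 cultures of mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, with 1 array per culture. The cultures came from embryos of a hybrid mouse background and of 2 genotypes: p53(-/-), with no intact allele of the tumour suppressor p53, and p53(246/-), with a mutant allele opposite a null allele. For each genotype 3 primary clones were profiled at early passage, together with the 3 clones obtained from them by transformation with E1A, an adenoviral protein that inactivates the retinoblastoma family, and the oncogene Ras. This gave 4 groups of 3 arrays, and the number of arrays limits the precision of each comparison. Whatever else differed between primary and transformed cultures, such as passage or cell make-up, goes with transformation here and was not separated from it. The values were read as log2 signal, with array medians from 5.44 to 5.59. Expression of Trp53 was not analysed here, so the genotypes rest on the labels.

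Transformation state separated the arrays. Correlation across probes was 0.979 to 0.991 between arrays of a group and 0.953 to 0.965 between arrays of different states. The first principal component held 68.7% of the variance, with primary cultures from -34.8 to -31.3 and transformed cultures from 29.98 to 35.8. The second held 10.3%, and on it p53(246/-) primary replicate 3 (25.8), p53(-/-) transformed replicate 1 (20.3) and p53(-/-) primary replicate 3 (14.8) stood apart from the others, which were at -0.46 or lower. These 3 arrays also had the narrowest spread of signal over probes, with SDs of 2.07, 2.08 and 2.11. The Y-linked genes Eif2s3y and Kdm5d matched between the primary and transformed culture of every clone. Eif2s3y was at 3.84 and 3.49 in the primary and transformed cultures of p53(-/-) replicate 3 and between 9.02 and 9.67 in all the others, and Kdm5d at 4.35 and 3.93 against 7.61 to 8.41. Y-linked signal was thus low in 1 p53(-/-) clone and 0 p53(246/-) clones, so sex-linked expression was unbalanced in every comparison of genotypes. The number before the hyphen in a clone's label, whose meaning is not given there, was shared by the 3 p53(-/-) clones and by 2 p53(246/-) clones, and 0 such numbers occurred in both genotypes.

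**Figure D1:**
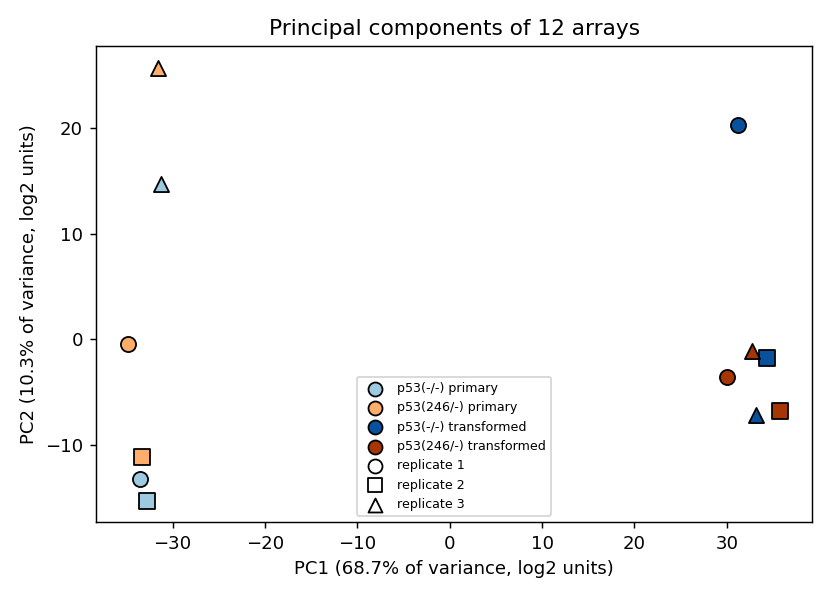
Scores of the 12 arrays on the first and second principal components (68.7% and 10.3% of the variance, log2 units); colour gives the group and shape the replicate. Primary cultures lie between -34.8 and -31.3 on the first component and transformed cultures between 29.98 and 35.8.

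The first comparison asked how transformation with E1A and Ras changed expression in cells without p53. In p53(-/-) cells Ifit1, an antiviral protein that binds foreign RNA, rose by 4.49 log2 units (SE 0.53, pooled over the 4 groups as are all SEs of single genes, n = 3 clones, adjusted p = 3.9e-05), the chemokine Ccl5 by 4.28 (SE 0.33) and the antiviral enzyme Rsad2 by 3.71 (SE 0.42). Hook1, an adaptor that links cargo to microtubules, rose by 4.05 (SE 0.13), Perp, a desmosomal protein, by 3.49 (SE 0.18) and the epithelial adhesion molecule Epcam by 3.45 (SE 0.17). Thy1, a surface glycoprotein of fibroblasts, fell by 5.28 (SE 0.21, adjusted p = 1.1e-08), and the tendon gene Tnmd fell by 5.02 (SE 0.13). The membrane protein Lrrc15 fell by 4.86 (SE 0.38), the collagen VI chain Col6a3 fell by 4.41 (SE 0.17), the matricellular protein Thbs2 fell by 4.18 (SE 0.28) and the microfibril protein Mfap5 fell by 4.17 (SE 0.25).

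In p53(-/-) cells 35 of the 36 measured genes of the fibroblast extracellular matrix fell and none rose, with 35 also adjusted over the list alone, a list median of -1.97 and an adjusted p of 8.5e-53 for the list. Of the contractile genes and targets of SRF and YAP, 17 of 25 fell (18 adjusted over the list alone), among them calponin, Cnn1, at -3.27 (SE 0.24), and Lmod1 at -1.63 (SE 0.12). The contractile list had a median of -0.96 and an adjusted p of 1.1e-13, or an adjusted p of 0.054 with an estimated correlation. Mesenchymal identity genes were lower (median -0.55, adjusted p = 1.8e-13), with 14 of 24 falling and 1 rising, against 14 and 2 adjusted over the list alone; the homeobox gene Prrx1 fell by 1.56 (SE 0.10). Of the epithelial genes, 6 of 20 rose and 1 fell, the same counts as adjusted over the list alone, and the keratin Krt18 rose by 1.83 (SE 0.14). The epithelial list had a median of 0.01, a mean of 0.28 and an adjusted p of 0.032, or 0.26 with an estimated correlation as an adjusted p. Its call was lost without p53(-/-) replicate 1, where the median was -0.05, and without the 3 arrays of narrowest spread, where it was -0.06. The sign of this median was not stable: it was 0.14 without p53(-/-) replicate 3 and without the dimmest probes, -0.0011 without p53(-/-) replicate 2, -0.04 after quantile normalization and -0.07 after median centring.

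Interferon-stimulated genes were higher after transformation of p53(-/-) cells: 24 of 26 rose (25 adjusted over the list alone), with a median of 2.01 and an adjusted p of 9.8e-15, or an adjusted p of 0.11 with an estimated correlation. The RNA sensor Ifih1 rose by 3.15 (SE 0.29) and the helicase Ddx60 by 3.58 (SE 0.34). Of the genes for MHC class I antigen presentation, 4 of 11 rose and 2 fell, against 6 and 2 adjusted over the list alone, with the peptide transporter Tap1 at 1.02 (SE 0.17) and the proteasome activator Psme1 at 0.87 (SE 0.11). The MHC class I list did not pass (median 0.42, adjusted p = 0.14) but passed without p53(-/-) replicate 1 (median 0.55) and without the 3 arrays of narrowest spread (median 0.59). Inflammatory cytokines and genes of the senescence secretome moved the other way. In that list 20 of 35 fell and none rose, also adjusted over the list alone, with a median of -1.004 (adjusted p = 2.3e-13); the adhesion molecule Vcam1 fell by 2.82 (SE 0.11) and Igfbp4 fell by 1.83 (SE 0.14). Macrophage and leukocyte markers, which belong to another cell type, also had a lower median of -0.89, with 10 of 15 falling (11 adjusted over the list alone), and the macrophage protease Ctss fell by 3.57 (SE 0.53, adjusted p = 0.00024). The adjusted p of the macrophage list was 0.0015, or an adjusted p of 0.44 with an estimated correlation, and its call was lost when the dimmest probes were left out, where the median was -1.67.

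Genes of DNA replication and E2F targets rose with transformation of p53(-/-) cells: 23 of 35 rose and 1 fell, also adjusted over the list alone, with a median of 0.48 and an adjusted p of 1.7e-06, or an adjusted p of 0.13 with an estimated correlation. The replication factor Mcm10 rose by 0.93 (SE 0.09) and Dscc1, which helps load the replication clamp, by 1.04 (SE 0.14), while the cyclin Ccne1 fell by 0.57 (SE 0.11). Of the mitosis genes 3 of 28 rose, also adjusted over the list alone, and the list did not pass (median 0.11, adjusted p = 0.23), though it passed after quantile normalization (median 0.17). Of the cyclin-dependent kinase inhibitors and pocket proteins, 3 of 10 rose and 2 fell, against 4 and 2 adjusted over the list alone, with Cdkn2a, the Ink4a/Arf locus, at 0.86 (SE 0.12) and Cdkn2c at 0.74 (SE 0.11). That list had a median of 0.37 and an adjusted p of 0.14, and it passed without p53(-/-) replicate 1 (median 0.52). Among genes of RAS and ERK output, 6 of 22 rose and 9 fell (6 and 11 adjusted over the list alone): the transcription factor Etv5 rose by 0.68 (SE 0.11), while the growth factor Ereg fell by 2.46 (SE 0.21) and the feedback inhibitor Spry4 fell by 0.86 (SE 0.11). The RAS list had a median of -0.31 and an adjusted p of 0.096, and it passed without p53(-/-) replicate 3 (median -0.40). The p53 target genes went both ways, with 6 of 36 rising and 6 falling, the same counts as adjusted over the list alone; the repair gene Ddb2 rose by 0.93 (SE 0.12), and the kinase Plk2 fell by 1.99 (SE 0.19). The median of the p53 target list was 0.06 and its adjusted p 0.55. Imprinted growth genes were lower, with 8 of 15 falling and 1 rising (9 and 2 adjusted over the list alone), a median of -0.35 and an adjusted p of 9.9e-06; the growth factor Igf2 fell by 3.98 (SE 0.19) and the noncoding RNA H19 fell by 2.98 (SE 0.34).

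In all, limma's moderated test called 3957 of 14860 genes in p53(-/-) cells, of which 2130 were higher and 1827 lower after transformation, and 895 changed at least 2-fold (307 higher and 588 lower). Centring each array on its median turned the split to 1363 higher and 2156 lower. The unmoderated mixed model called 2465 genes.

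The same comparison in p53(246/-) cells asked how transformation acted beside the mutant allele. Ifit1 rose by 5.46 (SE 0.53, n = 3 clones, adjusted p = 7.3e-06), Rsad2 by 5.33 (SE 0.42), Ccl5 by 5.22 (SE 0.33) and the ubiquitin ligase Trim30a by 5.16 (SE 0.63). Parp14, which acts on interferon signalling, rose by 4.57 (SE 0.47), the guanylate-binding protein Gbp3 by 4.33 (SE 0.38), the chemokine Cxcl10 by 4.18 (SE 0.39) and the antiviral GTPase Mx2 by 4.03 (SE 0.37). Tnmd fell by 4.82 (SE 0.13, adjusted p = 4.3e-10), Thy1 fell by 4.62 (SE 0.21) and the smooth muscle actin Actg2 fell by 4.57 (SE 0.38). The matrix proteoglycan Aspn fell by 4.33 (SE 0.27) and the membrane protein Plxdc2 fell by 4.28 (SE 0.29).

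The matrix list fell in p53(246/-) cells as well, with 34 of 36 genes lower (36 adjusted over the list alone), a median of -1.60 and an adjusted p of 4.1e-42; Col6a3 fell by 3.99 (SE 0.17) and the elastic fibre protein Fbln5 fell by 3.46 (SE 0.16). Of the contractile genes 20 of 25 fell (21 adjusted over the list alone; median -0.96, adjusted p = 7.1e-18), with Cnn1 at -3.75 (SE 0.24). Mesenchymal identity genes had a median of -0.44 (adjusted p = 3.8e-09), with 14 of 24 falling and 1 rising, against 15 and 1 adjusted over the list alone, and Prrx1 at -1.36 (SE 0.10). Of the epithelial genes 5 of 20 rose and 1 fell, also adjusted over the list alone, with Epcam at 3.44 (SE 0.17) and Krt18 at 2.48 (SE 0.14). The epithelial list had a median of 0.03, a mean of 0.27 and an adjusted p of 0.038, or an adjusted p of 0.32 with an estimated correlation. Its call was lost without p53(-/-) replicate 3 (median 0.03), without p53(246/-) replicate 1 (median -0.02) and without the 3 arrays of narrowest spread (median 0.04). The median was -0.0065 without p53(246/-) replicate 2, 0.07 without replicate 3 of that genotype, -0.01 after median centring, 0.05 after quantile normalization and 0.08 without the dimmest probes.

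All 26 interferon-stimulated genes rose in p53(246/-) cells, also adjusted over the list alone, with a median of 2.56 (adjusted p = 6e-28). Of the MHC class I genes 6 of 11 rose and 1 fell, against 7 and 2 adjusted over the list alone, with the immunoproteasome subunit Psmb8 at 1.99 (SE 0.27) and Tap1 at 1.27 (SE 0.17). The MHC class I list had a median of 0.72 and an adjusted p of 0.0056, or an adjusted p of 0.33 with an estimated correlation. Inflammatory and secretome genes were lower (median -0.67, adjusted p = 1.8e-06), with 18 of 35 falling and 2 rising, against 19 and 2 adjusted over the list alone. Vcam1 fell by 2.17 (SE 0.11), while the alarmin Il33 rose by 2.16 (SE 0.21). Beside these, 1 of 15 macrophage markers fell, also adjusted over the list alone, and that list did not pass (median -0.34, adjusted p = 0.17) but passed without p53(-/-) replicate 3 (median -0.34). DNA replication genes rose (24 of 35, with 1 falling, and 26 and 1 adjusted over the list alone), with a median of 0.59 and an adjusted p of 3.8e-09, or an adjusted p of 0.055 with an estimated correlation; Mcm10 rose by 1.01 (SE 0.09) and the polymerase subunit Pola1 by 0.80 (SE 0.08). Of the mitosis genes 10 of 28 rose (11 adjusted over the list alone), with Ect2, needed for cell division, at 0.54 (SE 0.09) and a list median of 0.26 (adjusted p = 0.020, or an adjusted p of 0.45 with an estimated correlation). Of the kinase inhibitors 5 of 10 rose, also adjusted over the list alone, with Cdkn2a at 1.02 (SE 0.12) and a list median of 0.54 (adjusted p = 0.026, or an adjusted p of 0.23 with an estimated correlation). Leaving out the dimmest probes or the 3 arrays of narrowest spread ended the calls of the mitosis list (medians 0.26 and 0.22) and of the kinase inhibitors (0.54 and 0.42), as did quantile normalization for the latter (0.45).

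Among genes of RAS and ERK output in p53(246/-) cells 7 of 22 rose and 9 fell, against 10 and 10 adjusted over the list alone, and the list did not pass (median -0.20, adjusted p = 0.66); Etv4 rose by 0.95 (SE 0.16), and the inhibitor Spry1 fell by 1.07 (SE 0.12). The p53 targets again went both ways, with 7 of 36 rising and 7 falling (8 and 8 adjusted over the list alone), Perp at 3.53 (SE 0.18) and Plk2 at -2.35 (SE 0.19). The p53 target list had a median of -0.01 and a mean of 0.04 (adjusted p = 0.59), so median and test differed in sign. Imprinted genes had a median of -0.40 (adjusted p = 0.00029), with 8 of 15 falling and 2 rising, against 9 and 2 adjusted over the list alone, and Igf2 at -3.82 (SE 0.19).

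In p53(246/-) cells limma called 4081 genes, 2390 higher and 1691 lower after transformation, of which 890 changed at least 2-fold (396 higher and 494 lower). After median centring the split was 1915 higher and 1907 lower. The count was 2608 without p53(246/-) replicate 1, 2571 without replicate 2 and 2688 without replicate 3 of that genotype, and 2528 in the unmoderated mixed model. At the preset correlation 14 of the 28 lists passed in each genotype. With an estimated correlation, the matrix, mesenchymal, inflammatory, imprinted and neural lists held in both genotypes, and the contractile and interferon lists held in p53(246/-) cells. Without the dimmest probes the medians in p53(-/-) and p53(246/-) cells were -0.87 and -0.87 for mesenchymal and -1.66 and -1.10 for inflammatory genes.

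**Figure D2:**
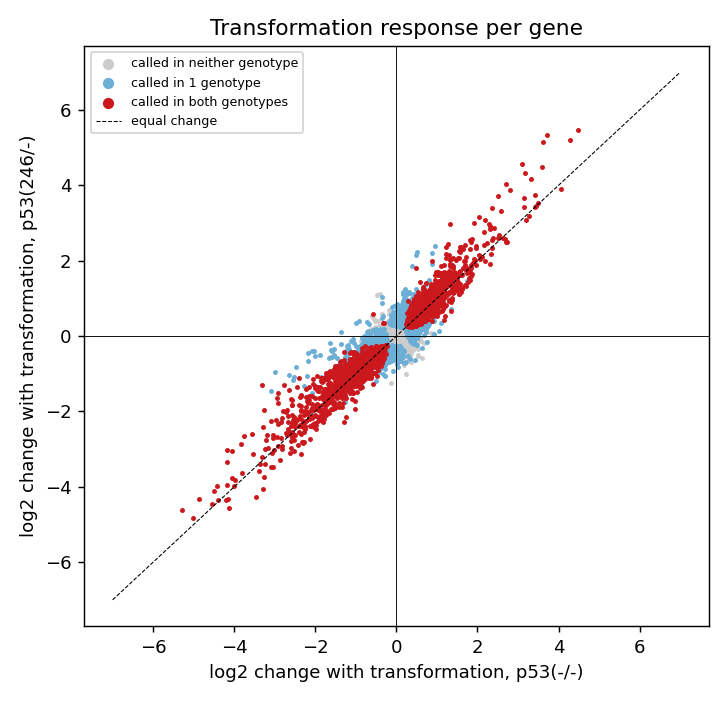
Log2 change with transformation per gene in p53(-/-) cells (x axis) and p53(246/-) cells (y axis), each the difference of 2 group means of 3 arrays; colour gives whether a gene was called in neither, 1 or both genotypes, and the dashed line marks equal change. Across genes r was 0.903.

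The responses of the 2 genotypes were then set side by side. Across genes the log2 changes correlated with r = 0.903 and rho = 0.770, with a slope of 0.911 of p53(246/-) on p53(-/-). Genes are not independent replicates; over the 9 pairs of a clone of each genotype, r had a mean of 0.777 and an SD of 0.0828. Both genotypes shared 1702 called genes that were higher and 1340 that were lower, where independent lists of these sizes would share 343 and 208, and 3 genes were called in opposite directions. Averaged over the genotypes, 5640 genes differed between transformed and primary cultures, 3223 higher and 2417 lower in the transformed ones. They were led by Ifit1 at 4.97, Ccl5 at 4.75, Thy1 at -4.95 and Tnmd at -4.92. Median centring turned the averaged split to 2447 higher and 3141 lower, and 880 genes changed at least 2-fold (329 higher and 551 lower).

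**Figure D3:**
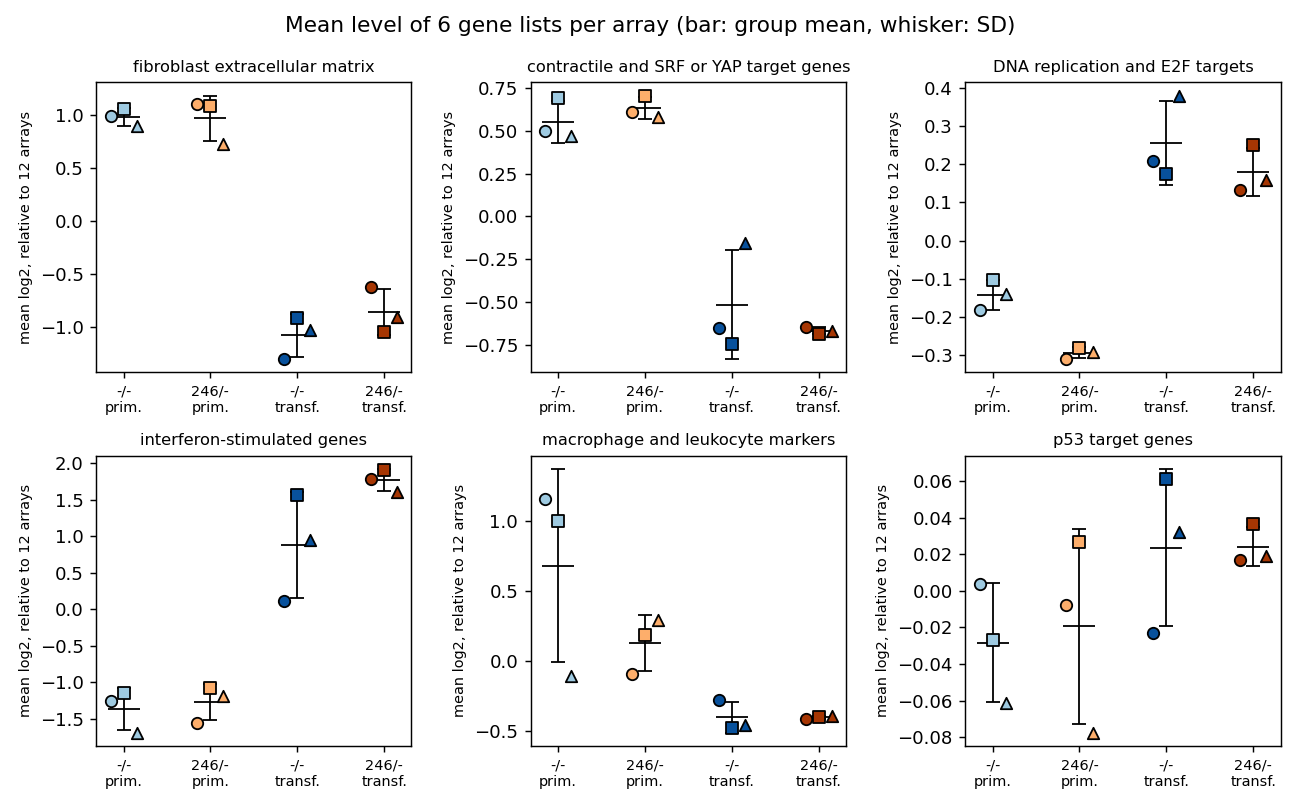
Mean log2 level of 6 gene lists in each array, relative to the mean of the 12 arrays; points are arrays (shape: replicate), bars group means and whiskers SDs over 3 arrays. The interferon list lies at 0.12, 1.57 and 0.95 in transformed p53(-/-) cells and from 1.61 to 1.91 in transformed p53(246/-) cells.

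In primary cells, the comparison of genotypes asked what the mutant allele changed before transformation. Kcnip1, a protein that binds potassium channels, was higher in p53(246/-) cells, at 6.39 against 5.26, a difference of 1.13 (SE 0.13, n = 3 clones per genotype, adjusted p = 0.014). It was the 1 gene that limma called; 823 genes had an unadjusted p under 0.05, and the unmoderated mixed model called 0. Inflammatory and secretome genes were lower in p53(246/-) cells by the list test (median -0.05, mean -0.22, adjusted p = 0.0014, and 0.0037 with an estimated correlation as an adjusted p). None of its 35 members passed over all genes, and 1 was higher and 6 lower adjusted over the list alone; the matrix protease Mmp3 was at -1.38 (SE 0.24, adjusted p = 0.14) and the growth factor Hgf at -1.05 (SE 0.24, adjusted p = 0.44). The mean level of that list was 6.44 (SD 0.05) in p53(-/-) and 6.22 (SD 0.05) in p53(246/-) cells, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. This p is unadjusted over the lists, and the DNA replication, mitosis and skeletal muscle lists had it too. The median of the inflammatory list was -0.01 without p53(-/-) replicate 2, -0.14 without p53(-/-) replicate 3, -0.14 without p53(246/-) replicate 2, -0.12 without the 3 arrays of narrowest spread and -0.20 without the dimmest probes.

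Of the 35 DNA replication genes, 3 had a higher mean in primary p53(246/-) than in primary p53(-/-) cells, with a list median of -0.13 (adjusted p = 8.7e-09), and mitosis genes also had a median of -0.13 (adjusted p = 3.6e-05). With an estimated correlation these adjusted p were 0.20 and 0.52, and no member passed, over all genes or adjusted over the list alone; the mitosis median was -0.07 without p53(-/-) replicate 2. Macrophage markers, of a cell type other than the fibroblast, moved with the genotype too, with a median of -0.56 and an adjusted p of 8.9e-06, or an adjusted p of 0.55 with an estimated correlation. The leukocyte antigen Ptprc was at -0.78 (SE 0.24, adjusted p = 0.68), and 1 member was higher adjusted over the list alone. The mean level of the macrophage list was 5.51 (SD 0.69) and 4.96 (SD 0.20), with an exact two-sided permutation p of 0.4. Its median was -0.27 without p53(-/-) replicate 1, -0.94 without p53(-/-) replicate 3, -0.97 without the dimmest probes and -1.07 without the 3 arrays of narrowest spread. p53 targets had a median of 0.02 in primary cells with the test pointing down (adjusted p = 0.98), and interferon-stimulated genes a median of 0.12 (adjusted p = 0.55). Matrix genes passed only without p53(246/-) replicate 3, with a median of 0.11 against 0.01.

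Kcnip1 lost its call in 6 of 17 alternatives, with adjusted p from 0.0036 to 0.67. The number of genes called in primary cells was 0 without p53(-/-) replicate 1 or 2 or without p53(246/-) replicate 1 or 2, 0 with the 6 primary arrays alone, and 38 without p53(-/-) replicate 3, with 2 higher and 36 lower in p53(246/-) cells. Of these 38 genes 7 were among the 15 macrophage markers; the clone left out had low Y-linked signal and the lowest macrophage markers of the p53(-/-) primary cultures, with Ctss at 6.29 against 8.86 and 8.51. The count was 45 (6 higher and 39 lower) without the 3 arrays of narrowest spread, which include that primary culture, 3 after quantile normalization, 2 without the dimmest probes and 2 with a trended, robust prior. With the replicate number as a block 3 genes were called, although the number pairs nothing across genotypes.

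In transformed cells no gene passed between the genotypes with limma or the unmoderated mixed model, while 846 genes had an unadjusted p under 0.05. The 5 genes with the smallest p all had an adjusted p of 0.0753 and higher levels in p53(246/-) cells. They were Il33 at 1.48 (SE 0.21), the exosome subunit Exosc9 at 0.68 (SE 0.10), Vcam1 at 0.70 (SE 0.11), Sertad3 at 0.80 (SE 0.12) and Tnfaip2 at 0.75 (SE 0.12). Interferon-stimulated genes were higher as a list, in 25 of 26 cases, with a median of 0.83 (adjusted p = 6e-30, and 0.027 with an estimated correlation as an adjusted p). No member passed over all genes and 16 did adjusted over the list alone; the nucleic acid sensor Zbp1 was at 1.49 (SE 0.34) and Mx1 at 0.67 (SE 0.15), both with an adjusted p of 0.40. Without p53(-/-) replicate 1 the median of the interferon list was 0.51, and its adjusted p with an estimated correlation 0.236. The mean level of the list was 7.72 (SD 0.73) in p53(-/-) and 8.61 (SD 0.15) in p53(246/-) cells, with an exact two-sided permutation p of 0.1. This p is unadjusted over the lists, and the inflammatory and skeletal muscle lists had it too. The fry test asks whether the members move on balance one way and compares them with no other genes. It gave an adjusted p of 0.31 for the interferon list.

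The inflammatory list was higher in transformed p53(246/-) cells (median 0.12, adjusted p = 0.00056, and 0.0026 with an estimated correlation as an adjusted p), with 2 members passing adjusted over the list alone and means of 5.33 (SD 0.02) and 5.48 (SD 0.09). MHC class I genes had a median of 0.25 (adjusted p = 1.2e-06) and genes of glycolysis and hypoxia one of 0.23 (adjusted p = 5.9e-08), each with an adjusted p of 0.11 with an estimated correlation; 2 MHC class I genes and 0 glycolytic genes passed adjusted over the list alone. The median of the MHC class I list was 0.10 without p53(-/-) replicate 1 and that of the inflammatory list 0.08; the latter was 0.07 without p53(-/-) replicate 2 and 0.05 without p53(246/-) replicate 1. The median of the glycolysis list was 0.09 without p53(246/-) replicate 1 and 0.36 without p53(246/-) replicate 3. Without the 3 arrays of narrowest spread, the medians were 0.10 for MHC class I, 0.08 for inflammatory and 0.51 for interferon-stimulated genes. Macrophage markers had a median of -0.03 here (adjusted p = 0.54), and p53 targets one of -0.0039 (adjusted p = 0.90); in both lists the mean and the test pointed up, against the sign of the median. Of the 12 lists called at the preset correlation, the interferon and inflammatory lists held with an estimated one. The other 8 were RAS output (median 0.12, adjusted p = 0.00011), matrix (0.13, 3e-05), cholesterol synthesis (0.16, 0.00013), imprinted (0.10, 0.0034), mesenchymal (0.13, 0.0057), NRF2 targets (0.06, 0.0094), contractile (-0.12, 0.0094) and DNA replication (-0.06, 0.024). With an estimated correlation their adjusted p ran from 0.11 to 0.64. Adjusted over the list alone, 4 RAS genes, 1 imprinted and 1 cholesterol gene passed.

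Each of these 8 calls was lost on leaving out 1 clone. Without p53(-/-) replicate 1 the medians were 0.10 for RAS output, 0.04 for matrix, 0.05 for mesenchymal, 0.06 for imprinted, 0.08 for cholesterol and 0.04 for NRF2 genes; these 6 calls were also lost, with the same medians to 2 decimals, without the 3 arrays of narrowest spread. Without p53(-/-) replicate 3 those of DNA replication and contractile genes turned to 0.00045 and 0.0094. Without p53(246/-) replicate 1 matrix (0.04), mesenchymal (0.10) and DNA replication genes (-0.03) lost their calls, without replicate 2 of that genotype NRF2 targets (0.04), and without replicate 3 DNA replication genes (-0.06). Other medians moved by over 1.5 times with the call kept: contractile genes (-0.23) without p53(-/-) replicate 1, contractile genes (-0.22) without replicate 2 of that genotype, and RAS (0.19), matrix (0.22) and NRF2 genes (0.13) without its replicate 3. Without p53(246/-) replicate 1 these were imprinted (0.04) and NRF2 genes (0.10), without its replicate 2 matrix (0.24), contractile (-0.06) and mesenchymal genes (0.08), and without its replicate 3 RAS (0.20) and mesenchymal genes (0.06). After median centring the median of DNA replication genes was -0.027, with the call kept. The count of called genes was 25 without p53(-/-) replicate 2 and 11 after quantile normalization, and 1 both without the 3 arrays of narrowest spread and with the 6 transformed arrays alone. Il33 passed in 2 of its alternatives, with adjusted p from 0.0060, without p53(-/-) replicate 2, to 0.82.

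The difference in response asked whether transformation acted differently beside the mutant allele. No gene passed with limma, with 769 at an unadjusted p under 0.05, and the unmoderated mixed model called 1. The 5 smallest p belonged to Mertk, a receptor for dying cells, at 1.32 (SE 0.21), Il33 at 1.67 (SE 0.29), Sertad3 at 0.98 (SE 0.17) and Kcnip1 at -0.99 (SE 0.18), each with an adjusted p of 0.42, and the apoptosis regulator Cflar at 0.72 (SE 0.15, adjusted p = 0.76). Kcnip1 lay at 3.85 to 4.23 in the transformed cultures, below the lower quartile of signal of each array (4.28 to 4.53). Its value here therefore mostly mirrors the difference in primary cells. The inflammatory list fell less in p53(246/-) cells, with a median difference of 0.25 (adjusted p = 1.4e-06, and 1.3e-06 with an estimated correlation as an adjusted p). Adjusted over the list alone 6 members were higher and 1 lower, Mmp3 was at 1.51 (SE 0.34, adjusted p = 0.76), and the list means fell by 1.11 (SD 0.04) and fell by 0.73 (SD 0.09), with an exact two-sided permutation p of 0.1. The interferon, MHC class I, glycolysis and NRF2 lists had the same permutation p, unadjusted over the lists. Interferon-stimulated genes differed by a median of 0.72 (adjusted p = 2.5e-12) and macrophage markers by 0.55 (adjusted p = 0.00022), with adjusted p of 0.33 and 0.44 with an estimated correlation and no member passing adjusted over the list alone. The inflammatory median was 0.04 without p53(246/-) replicate 3, 0.15 without p53(-/-) replicate 2, 0.39 without p53(-/-) replicate 3, 0.38 without p53(246/-) replicate 2, 0.15 without the 3 arrays of narrowest spread and 0.59 without the dimmest probes. The interferon median was 0.45 and the macrophage median 0.34 without p53(-/-) replicate 1; the latter was 0.85 without p53(-/-) replicate 3. In all 13 of 28 lists passed at the preset correlation, 1 with an estimated one and 0 by fry. The p53 target list had a median of -0.01 with the test pointing up (adjusted p = 0.93). The count of called genes was 12 without p53(-/-) replicate 3 (all higher, 2 of them macrophage markers), 1 without p53(-/-) replicate 2 and 19 without the 3 arrays of narrowest spread.

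Averaged over both states, limma called 6 genes between the genotypes with the 2 arrays of a clone as separate values, and 0 with 1 value per clone. Exosc9 had a higher mean in p53(246/-) cells by 0.71 (SE 0.07, n = 3 clones per genotype, each measured in both states, adjusted p = 0.0049), the nucleotide hydrolase Entpd4 by 0.65 (SE 0.08, adjusted p = 0.013) and the ciliary gene Bbs7 by 0.63 (SE 0.09, adjusted p = 0.020). The ciliary transport gene Ift57 had a lower mean, at -0.69 (SE 0.09, adjusted p = 0.020), as was the sorting nexin Snx4 at -0.51 (SE 0.07, adjusted p = 0.019). Kcnip1, named because it is the remaining called gene, was at 0.63 (SE 0.09, adjusted p = 0.027), with overlapping groups in transformed cells. Its signal there was below the lower quartile of each array, so its call rests on primary cells. The consensus correlation of -0.0021 means that this fit took the 2 arrays of a clone as nearly independent. With their mean as 1 value per clone the adjusted p of the 6 genes were 0.12 to 0.30, and 751 genes had an unadjusted p under 0.05; with the label number as a random block 3 genes were called, Exosc9, Entpd4 and Snx4. Over all alternatives the adjusted p of the 5 genes other than Kcnip1 ran from 0.0024 to 0.93. The unmoderated mixed model called 0 genes, none of the 6 changed 2-fold, and the count was 0 without p53(-/-) replicate 1 or 2 or p53(246/-) replicate 2, 1 without p53(246/-) replicate 1, 20 without p53(-/-) replicate 3 (4 higher and 16 lower, with 4 of the 6 genes and 3 macrophage markers among them) and 28 without the 3 arrays of narrowest spread. Over all genes the genotype difference in primary cells and that in transformed cells correlated with r = 0.00276 (rho = -0.0327), with an SD of 0.184 over 9 pairs of clones; r was 0.226 without p53(-/-) replicate 1 and -0.230 without p53(-/-) replicate 3.

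**Figure D4:**
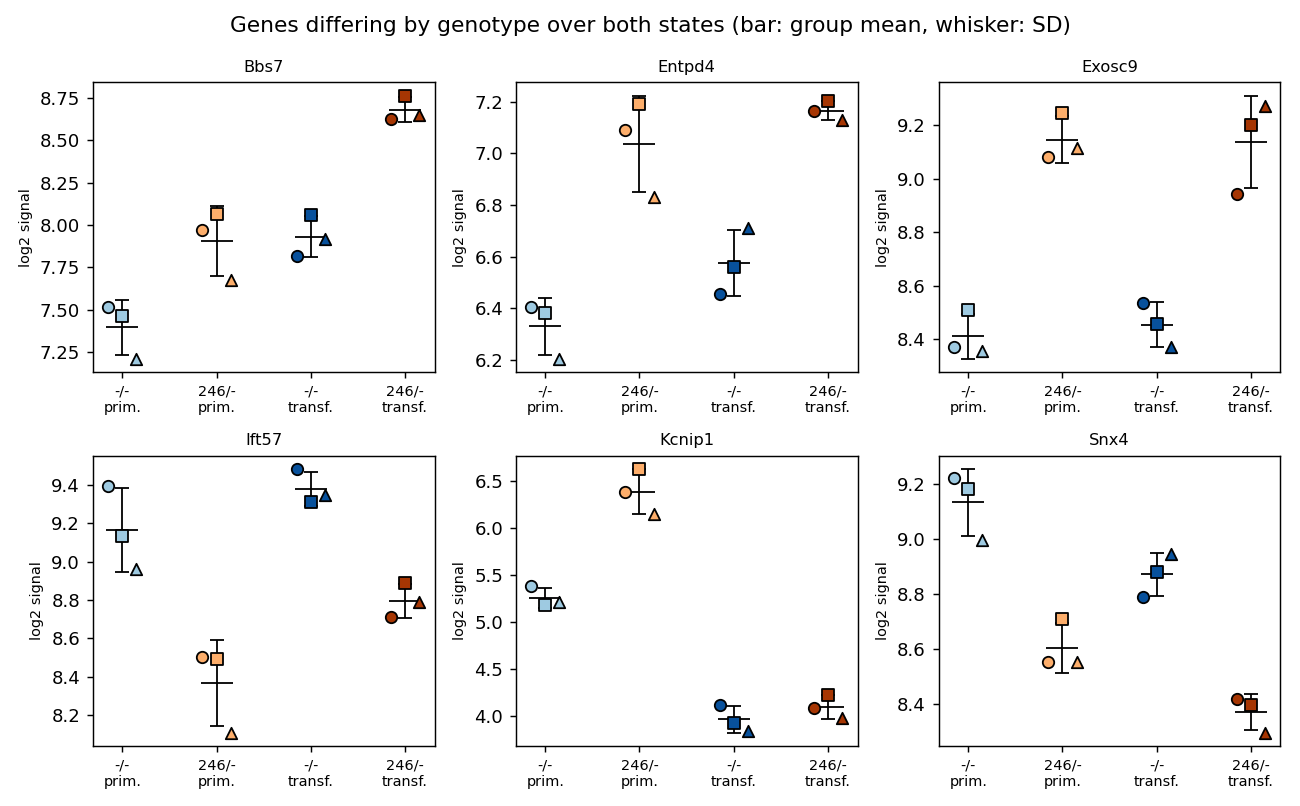
Log2 signal of the 6 genes called between the genotypes over both states with arrays as separate values, per array; points are arrays (shape: replicate), bars group means and whiskers SDs over 3 arrays. Exosc9 lies near 8.4 in both p53(-/-) groups and near 9.1 in both p53(246/-) groups, and Kcnip1 has its difference in primary cells, at 6.39 against 5.26.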

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

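The tests of a single clone with low levels, of a narrower signal range and of varying macrophage content were chosen after the results were seen, and the bound of the single-clone test was set after its value was known; the other tests here were fixed before.

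The lists below differed between the genotypes in their response to transformation by camera at the preset correlation, each as the median over its genes of the p53(246/-) minus the p53(-/-) log2 response. Interferon-stimulated genes differed by 0.724, macrophage markers by 0.555, glycolysis and hypoxia genes by 0.309, inflammatory and secretome genes by 0.249 and MHC class I genes by 0.243. Cholesterol synthesis genes differed by 0.218, NRF2 targets by 0.173, RAS and ERK output by 0.124, matrix genes by 0.121, mitosis genes by 0.104, DNA replication genes by 0.0946, mesenchymal genes by 0.0753 and contractile genes by -0.194. With an estimated correlation the inflammatory list alone held among the 28 tested; the adjusted p of the other 12 of these 13 ran from 0.22 to 0.63. Leaving out 1 clone ended the calls of 9. Without p53(-/-) replicate 1 these were DNA replication (0.067), RAS (0.109), matrix (-0.0011), mesenchymal (0.079), MHC class I (0.042) and cholesterol genes (0.057). Without p53(-/-) replicate 2 they were DNA replication (0.040), mitosis (0.033) and RAS genes (0.044), and without p53(-/-) replicate 3 contractile (-0.031, with the test turned) and mesenchymal genes (0.066). Without p53(246/-) replicate 2 they were DNA replication (0.065), contractile (-0.118) and NRF2 genes (0.126), and without p53(246/-) replicate 3 mitosis (0.091), matrix (0.030), mesenchymal (0.013) and cholesterol genes (0.113). Medians that moved by over 1.5 times with the call kept were, without p53(-/-) replicate 1, interferon (0.451), macrophage (0.339) and NRF2 genes (0.115), and without p53(-/-) replicate 2 inflammatory (0.147) and contractile genes (-0.308). On leaving out p53(-/-) replicate 3 they were DNA replication (0.151), mitosis (0.195), RAS (0.293), matrix (0.195), inflammatory (0.392) and macrophage genes (0.853). Without p53(246/-) replicate 1 this was matrix (0.072), without its replicate 2 RAS (0.081), matrix (0.250) and inflammatory genes (0.382), and without its replicate 3 inflammatory genes (0.041). Quantile normalization ended the calls of DNA replication (0.045), mitosis (0.049), RAS (0.074), matrix (0.107) and cholesterol genes (0.164), and leaving out the dimmest probes ended these 5 and that of NRF2 genes. Leaving out the 3 arrays of narrowest spread ended those of DNA replication (0.034), mesenchymal (0.011), cholesterol (0.062), NRF2 (0.071) and matrix genes, which turned to -0.034. Without these arrays the medians were 0.482 for interferon, 0.113 for MHC class I, 0.146 for inflammatory and 1.09 for macrophage genes.

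Signals outside the named genes were also found. Of 8336 probes without a single gene name, transformation changed 356 in p53(-/-) cells (212 higher and 144 lower) and 327 in p53(246/-) cells (210 and 117). For genotype and for the difference in response limma called 0 of these probes, with 410 in primary cells, 370 in transformed cells and 366 for the difference at an unadjusted p under 0.05; the unmoderated model was not run on them.

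Interferon-stimulated genes were higher in transformed p53(246/-) than in transformed p53(-/-) cells, by a median of 0.83, with relative list means of 1.78, 1.91 and 1.61 against 0.12, 1.57 and 0.95. The tables argue against the narrow signal range of p53(-/-) transformed replicate 1, the lowest of these: the list lay at -1.14 against the other clones of its group, while the lowest of 10000 random lists matched on mean level lay at -0.294, a share of 0.01%, the smallest they can give. Without p53(-/-) replicate 1 the median was 0.51, and the adjusted p of the list by camera was 2.9e-13 (0.236 with an estimated correlation). The difference between genotypes of the clones' list means, a different measure, then had an SE of 0.323. Since the median lies within 2 of these SEs of 0, a single low clone and a difference between genotypes cannot be told apart. This bound replaced an earlier one on the median alone, above which 0.51 lay. Of the 10 splits of the 6 clones 3, the real one among them, gave a median as large, the highest other being 0.854. By this measure the spread between clones may account for it. On list means no other split was as large, with an exact two-sided permutation p of 0.1, unadjusted over the lists and the smallest that 3 against 3 allows. The p53 allele also stays open, as an untested explanation. What the number before the hyphen in the clone labels marks cannot be told apart from genotype, and the splits take the clones as exchangeable.

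Macrophage markers were lower in primary p53(246/-) than in primary p53(-/-) cells, with relative list means of -0.10, 0.19 and 0.29 against 1.15, 0.99 and -0.11; among the most abundant, Ctss was at 8.86, 8.51 and 6.29 and Tyrobp at 7.66, 7.60 and 4.91 in p53(-/-), against 5.85, 6.85 and 7.36 and 4.77, 5.89 and 5.69 in p53(246/-) cultures. Cultures may have held differing shares of macrophages: the markers deviated together within the primary groups, with a mean pairwise correlation of 0.661 against a 95th percentile of 0.411 and a highest value of 0.772 over 10000 matched random lists. The markers and arrays were those that raised the question, so a high correlation was likely beforehand and does not settle it. Of the 15 markers 0 are in another list, and Cd68 was at 7.15 and 7.07 in transformed p53(-/-) and p53(246/-) cells, where the list was lowest; no sort that would remove macrophages is named in the labels. A lower share of fibroblasts cannot be told apart from this, since the difference from the mean of 7 other marker lists, -0.599, had an SE of 0.433. The mean of the macrophage list differed by -0.551 between the genotypes. Those of the 7 other lists differed by -0.035 (neural and glial) to 0.105 (erythroid). The genotype of the embryo stays open as an untested explanation.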

How the results depend on the processing

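Leaving out the 3 arrays of narrowest spread, the lists after median centring, the label number as a random block and 1 value per clone were chosen after seeing the data; the other alternatives were fixed before. No named gene that was called in the reported fit or in an alternative turned direction in that alternative. Named genes called in neither were not counted, and these could change sign. Eif2s3y had a higher mean in primary p53(246/-) than p53(-/-) cells, but a lower one without p53(-/-) replicate 3. The unmoderated mixed model called 2465 genes for transformation in p53(-/-) and 2528 in p53(246/-) cells, 0 for genotype in primary cells and averaged over states, and 1 for the difference in response. Asking for a 2-fold change left 895, 890 and, averaged over genotypes, 880 genes for transformation and 0 for genotype averaged over states, by its construction. For genotype in primary cells quantile normalization called 3 genes, leaving out the lowest 33.3% of probes 2, a trended and robust prior 2 and the 6 arrays alone 0, and without the 3 arrays of narrowest spread 45 (6 higher and 39 lower). For genotype in transformed cells quantile normalization called 11 and the 6 arrays alone 1, and without the 3 arrays of narrowest spread 1. Those 3 arrays left out, 19 genes were called for the difference in response and 28 for genotype averaged over states. Leaving out each clone gave 2571 to 4924 genes for transformation in p53(246/-) cells, 0 to 38 and 0 to 25 for genotype in primary and transformed cells, 0 to 12 for the difference in response and 0 to 20 for genotype averaged over states; the 25 came without p53(-/-) replicate 2, and the 38, 12 and 20 without p53(-/-) replicate 3. For genotype averaged over states 1 value per clone called 0 genes, with fewer values in the fit, and the label number as a random block 3. The correlation of the genotype differences ran from -0.230 to 0.226. Over all comparisons 87 list calls fell to 23 with an estimated correlation, since genes of a list vary together. Otherwise the cause was not tested.

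Counts within 1.5 times of those reported in every clone left out were 2710 to 4055 for transformation in p53(-/-) cells and 4621 to 5731 averaged over genotypes. With the clone as a fixed replicate block (the replicate number for genotype) the counts were 3680 and 3829 for transformation in p53(-/-) and p53(246/-) cells, 3, 0 and 0 for genotype in primary cells, in transformed cells and the difference in response, and 5417 and 9 for the averages; pairing ended 9 calls among named genes, made 1, moved the count for genotype in primary cells from 1 to 3, and left the other 6 counts within 1.5 times. Without a block the counts were 3963, 4087, 1, 0, 0, 5643 and 6.

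Some lists turned direction. In transformed cells, leaving out each clone gave -0.081 to 0.00045 for the genotype difference of DNA replication genes and -0.233 to 0.0094 for contractile genes. For the difference in response it gave -0.308 to -0.031 for contractile genes, where the test turned and not the median, and -0.141 to 0.172 for amino acid response genes; averaged over states the latter ran from -0.042 to 0.121. Without the 3 arrays of narrowest spread the difference in response was -0.034 for matrix genes and 0.014 for adipocyte markers. Over the 28 lists and 7 comparisons, 64 list calls were lost and 0 gained with an estimated correlation, and by fry 43 were lost and 23 gained, leaving 67. Losses and gains were 12 and 4 after quantile normalization, 20 and 5 without the dimmest probes, 4 and 2 after median centring, 24 and 6 without the 3 arrays of narrowest spread, and 7 to 25 and 4 to 9 on leaving out 1 clone, apart from the calls that turned direction. Of the calls of named genes, 49 were lost in the unmoderated model, 9 with the block, 8 with the 6 arrays alone, 7 after median centring, 5 with 1 value per clone, 2 with the label number as a block and 5 to 28 on leaving out 1 clone. Calls of named genes were gained after quantile normalization (5, with 4 lost), without the 3 arrays of narrowest spread (6, with 4 lost), after median centring (2), without the dimmest probes (1), with the 6 arrays alone (1), and without p53(-/-) replicate 2 (6) or 3 (7). All alternatives fixed before were run. The array number limits small effects, and signal over background is unknown.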

Other observations

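The tests of chance placement of genes and of the clone of low Y-linked signal were chosen after the result was seen; the others here were fixed before.

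Transformation also changed genes of metabolism and patterning. Cholesterol synthesis genes were lower in p53(-/-) cells, with 9 of 17 falling (12 adjusted over the list alone), a median of -0.53 and an adjusted p of 5.2e-05 (adjusted p = 0.12 with an estimated correlation), and the sterol oxidase Msmo1 at -1.08 (SE 0.12). In p53(246/-) cells 9 fell too, also adjusted over the list alone, with a median of -0.39 (adjusted p = 0.0086, and 0.33 with an estimated correlation as an adjusted p). NRF2 targets had a median of -0.29 in p53(-/-) cells (adjusted p = 0.011, and 0.092 with an estimated correlation as an adjusted p), with 6 of 16 falling (8 adjusted over the list alone), among them the glutathione conjugate pump Abcc1 at -1.12 (SE 0.12); in p53(246/-) cells 3 fell, also adjusted over the list alone, and the list did not pass (median -0.23, adjusted p = 0.20). Glycolysis and hypoxia genes went both ways, with 2 of 21 rising and 6 falling in p53(-/-) cells (median -0.13, adjusted p = 0.13) and 3 rising and 3 falling in p53(246/-) cells (median 0.09, adjusted p = 0.72), the same counts as adjusted over the list alone: the glucose transporter Slc2a3 rose by 1.19 (SE 0.17) in p53(-/-) cells, where the collagen hydroxylase P4ha1 fell by 1.14 (SE 0.15). Amino acid response genes did not pass as a list (medians -0.15 and -0.12, adjusted p = 0.38 and 0.59; 1 rising and 2 falling of 22, and 1 and 3), with the stress factor Atf3 rising by 1.48 (SE 0.19) in p53(-/-) cells, nor did ribosome biogenesis genes (medians 0.09 and 0.02, adjusted p = 0.44 and 0.59; 2 and 3 of 25 rising).

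Of the Hox genes, which pattern the body axis, 8 of 32 rose in p53(-/-) cells, also adjusted over the list alone, with Hoxa5 at 1.38 (SE 0.19) and Hoxd9 at 0.65 (SE 0.08), a median of 0.21 and an adjusted p of 0.031 (adjusted p = 0.45 with an estimated correlation); the call was lost after quantile normalization (median 0.12) and without the dimmest probes (median 0.19), and the median was 0.12 after median centring. In p53(246/-) cells 7 rose and 2 fell, against 8 and 2 adjusted over the list alone, and the list did not pass (median 0.18, adjusted p = 0.10) except without p53(246/-) replicate 2 (median 0.22). Genes reported to be raised by mutant p53, a list that shares members with others, had a median of -0.26 in p53(-/-) cells (3 of 20 rising and 9 falling, 5 and 9 adjusted over the list alone; adjusted p = 0.020, and 0.26 with an estimated correlation as an adjusted p), lost after quantile normalization (-0.28), without the dimmest probes (-0.26) and without p53(-/-) replicate 2 (-0.16). In p53(246/-) cells the median was -0.27 (adjusted p = 0.090; 5 rising and 8 falling, 6 and 8 adjusted over the list alone), and it passed without p53(246/-) replicate 3 (-0.26) and without the 3 arrays of narrowest spread (-0.31). The drug exporter Abcb1b rose by 0.85 (SE 0.13) and the growth factor receptor Pdgfrb fell by 2.39 (SE 0.20) in p53(-/-) cells. Between the genotypes that list had medians of -0.01 in primary (adjusted p = 0.37) and 0.02 in transformed cells (adjusted p = 0.73).

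Markers of other cell types were measured in both genotypes. Neural and glial markers fell as a list with transformation (7 of 15 falling and 1 rising in p53(-/-), 4 falling in p53(246/-) cells, also adjusted over the list alone; medians -0.22 and -0.20, adjusted p = 0.00014 and 0.00055, held with an estimated correlation); without the dimmest probes the medians were -0.76 and -0.32, and in p53(-/-) cells -0.33 without p53(-/-) replicate 1 and -0.35 without the 3 arrays of narrowest spread. The fatty acid carrier Fabp7 fell by 4.50 (SE 0.26) and Stmn2 fell by 4.20 (SE 0.29) in p53(-/-) cells. Endothelial markers had medians of -0.07 in p53(-/-) (adjusted p = 0.065) and -0.14 in p53(246/-) cells (adjusted p = 0.027, and 0.42 with an estimated correlation as an adjusted p), with 4 of 15 falling in each; the latter call was lost without p53(246/-) replicate 3 (-0.13) and without the dimmest probes (-0.48), and the former passed without p53(-/-) replicate 1 (-0.14) or 2 (-0.14), after quantile normalization (-0.15) or median centring (-0.16) and without the 3 arrays of narrowest spread (-0.07). After quantile normalization the endothelial median in p53(246/-) cells was -0.08, with the call kept. Skeletal muscle markers had medians of -0.04 and -0.15 (adjusted p = 0.12 and 0.10), with Pax3 rising by 1.58 (SE 0.25) and Acta1 falling in p53(-/-) cells at -1.87 (SE 0.20), and cartilage and bone markers -0.06 and -0.15 (adjusted p = 0.13 and 0.070), with Col11a1 at -2.17 (SE 0.16) and a pass in p53(-/-) cells without p53(-/-) replicate 1 (-0.19). Adipocyte markers had medians of 0.06 and -0.15 (adjusted p = 0.28 and 0.27), with a mean of -0.25 in p53(-/-) cells against the sign of the median. Erythroid markers had medians of 0.06 and -0.10 (adjusted p = 0.55 and 0.73). Keratinocyte markers had medians of -0.03 and -0.13 with means of 0.27 and 0.17, since Perp is among them (adjusted p = 0.14 and 0.35), and the list passed without the dimmest probes (medians 0.16 and 0.18) and, in p53(-/-) cells, without the 3 arrays of narrowest spread (-0.03). The p53 family, with 2 of 3 genes measured, was too small to test as a list: in p53(-/-) cells Trp63 was at -0.05 (SE 0.09) and Trp73 at -0.05 (SE 0.12), neither passing. Sex-linked genes, with 2 of 6 measured, were used as a check alone.

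Some results of the genotype comparisons differed in sign between median, mean and test. In primary cells matrix genes had a median of 0.01 and a mean of -0.01 (adjusted p = 0.92). For the difference in response adipocyte markers had a median of -0.15 and a mean of 0.05, and neural markers -0.13 and 0.06 (adjusted p = 0.88 and 0.74). Averaged over states 14 lists passed at the preset correlation and 0 with an estimated one, led by interferon-stimulated genes at 0.48 (adjusted p = 1.4e-16, and 0.30 with an estimated correlation as an adjusted p) and DNA replication genes at -0.09 (3.6e-09 and 0.30). The interferon median was 0.18 without the 3 arrays of narrowest spread.

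Other splits of the samples gave fewer genes for transformation averaged over the genotypes. Of 100 drawn from 200 splits 1, the real one with 5640 genes, gave as many, and the highest other gave 2. The 15 drawn that part all 6 pairs of a clone, as the real split does, gave at most 2. A share of 1 in 100 makes chance unlikely there but does not exclude it. The other splits put primary and transformed arrays into the same group, which widens the spread within groups. Low counts were therefore likely for them beforehand. In every other comparison 10 splits are too few for a share under 0.05. The real value and the highest of the others were 3957 and 0 for transformation in p53(-/-) cells (1 split as large), 4081 and 0 in p53(246/-) cells (1), 1 and 1 for genotype in primary cells (3), 0 and 1 in transformed cells (10), 0 and 0 for the difference in response (10), and 6 and 3 for genotype averaged over states (1). The genotype splits take the clones as exchangeable, while no label number is shared between the genotypes.

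Of the 6 genes called by genotype over both states, of which 0 were called with 1 value per clone, Exosc9 and Bbs7 lie 2 places apart in gene order. Of 10000 draws of 6 among 14833 placed genes 0.34% held a pair as close, but the distance was taken from this pair, so chance placement stays open. Without p53(-/-) replicate 3, the 1 clone of low Y-linked signal, the 6 genes kept their direction. The smallest difference was then 4.89 SEs over the clones. The genes were called on the same arrays, and a difference coming from 1 clone alone could hardly have been called there. This outcome was therefore nearly fixed in advance. The values only describe the 6 differences in the remaining clones, and no conclusion on the sex of the clones is drawn from them. A candidate explanation is a lasting difference between embryos or litters, such as strain segments around a gene in a hybrid background. Of the 20 genes with the largest statistic in primary cells, 15 kept their sign in transformed cells. Of the 10 splits of the clones 3, the real one among them, kept as many, the highest other keeping 19 and the lowest 5. With other splits on both sides, this test cannot decide. Over all genes, the genotype differences of the 2 states correlated at r = 0.00276. The other splits gave -0.316 to 0.452, and 6 of the 10, the real one among them, were as high. The p53 allele and whatever the label number marks lie with genotype in these 6 clones, so these values do not part them. They stay open, as do probes that read strain variants, which were not tested.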
